A study of Mus musculus with 12 samples.

How the data were processed

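Polyadenylated RNA of 3T3-L1 cells was sequenced in 12 stranded libraries, 4 groups of 3, defined by the construct the cells carried (FHL2-GFP or control GFP) and by the day (0 or 2 of adipogenic induction). Group membership came from the sample labels alone, and the labels do not say how the 3 libraries of a group were obtained. The values are raw counts per Ensembl gene identifier, as deposited by the authors in a single table with 1 column per library. The labels name GRCm39 (mm39) as the genome build, and FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, HTSeq 0.11.0, R 4.1.0 and limma as tools. The order and settings of these tools, the annotation release and the strand setting are not given in the sources used here. The table held 55414 identifiers, 52081 of which had a gene symbol in the gene name table used.

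The depth ranged from 10047708 to 21872139 counts per library. Intervals and floors cover counting error only, since reads were not tagged by molecule. A gene without a count in any library of a group was given a floor of 3 counts over the group, and its fold is stated as a lower bound against that floor. Levels are counts-per-million (CPM) values after TMM scaling of the library totals.

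Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which left 14435 genes. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries at once. The 5 comparisons were FHL2 against control at day 0 and at day 2, day 2 against day 0 in control and in FHL2, and the interaction, in which the day 0 difference between the lines is subtracted from the day 2 difference. P-values are from edgeR unless another tool is named, are 2-sided, and were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.123 over the day 0 libraries, 0.463 over the day 2 libraries and 0.283 over all libraries. A single estimate of spread is therefore shared by days that differ in it.

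Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives not marked otherwise. There were 25 lists: adipogenic transcription factors, mature adipocyte genes, preadipocyte and anti-adipogenic genes, NFAT5 and tonicity response genes, S phase and DNA replication, G2 and mitosis, collagens and extracellular matrix, matrix proteases and inhibitors, actin cytoskeleton and SRF targets, YAP and TEAD targets, Wnt and beta-catenin targets, inflammatory and NF-kB genes, interferon-stimulated genes, glucocorticoid and cAMP response genes, cholesterol biosynthesis, p53 targets, the unfolded protein and integrated stress response, circadian clock, mitochondrially encoded genes, the FHL family, and markers of muscle, bone and cartilage, macrophages and blood, endothelium and epithelium. The 21 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, and p-values were adjusted over the lists within a comparison. Member counts come from the gene test, adjusted over all genes tested and, separately, over the list alone. A list that passed was also tested with a correlation estimated from its genes.

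Named genes were chosen by rule. Fhl2, Nfat5, Pparg, Cebpa, Cebpb, Cebpd, Fabp4, Adipoq, Dlk1, Akr1b3, Slc5a3, Slc6a6, Slc6a12, Col1a1 and Mki67 were always considered. Each comparison added the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM over the groups compared, a symbol that is not a Gm, Rik or pseudogene name, and no overlap between the libraries of the groups. The overlap condition was not applied to the interaction. Each list added up to 3 called members with the largest absolute log2 fold change and a mean of at least 5 CPM. All lists did so for FHL2 against control, and the first 6 lists and the glucocorticoid list for the other comparisons. Slc6a12 had too few counts to be tested. Not every gene that the rule took is printed.

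The difference between days followed the GC content of genes, so GC content and transcript length were taken by gene identifier from GENCODE M21, an annotation of the previous build, which held 99.8% of the tested genes. No coordinates are given, since no annotation of GRCm39 was at hand. A correction added a smooth offset per library that follows GC content, and another added transcript length. These were chosen after seeing the data, as were a fit without the 3 day 2 libraries in which the fewest genes were detected, a minimum mean of 5 CPM, the list tests in fits of only the groups compared, and the estimated correlation after the correction for GC content. Alternatives fixed in advance were RLE and upper-quartile scaling, no filter on low counts, 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, only the libraries of the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, leaving out each library in turn, camera with an estimated correlation, and fry. Where leaving out libraries left a group with 1 library, its spread was assumed to be that of the other groups.

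The procedure was tested on simulated data with the depth and spread of these libraries and 200 changed genes. In the comparison of the lines at day 2, the model recovered 24.6%, 57.8% and 91.7% of genes changed 1.5-fold, 2-fold and 4-fold, and called 75 to 106 unchanged genes. A fit of the day 2 libraries alone recovered 13.4%, 47.0% and 85.6% and called 3 to 7 unchanged genes. At day 0 the recovered shares were 17.5%, 59.0% and 93.2%, with 0 to 1 unchanged genes called, and the fit of the day 0 libraries alone recovered 70.5%, 95.1% and 100% and called 14 to 18 unchanged genes. For the interaction they were 1.49%, 34.0% and 73.9%, with 7 to 14 unchanged genes called. Camera called a simulated changed list in 4 of 4 runs and 0 of 80 unchanged lists. The simulated genes varied independently, and changed ones at least 1.5-fold, so list calls with genes that vary together or change less were not tested. With a simulated GC trend between the days, the uncorrected model called 6492 genes that had no other change and the corrected model 10. Of 200 changed genes they called 157 and 114.

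Other splits of the same libraries were fitted for each count of genes or lists, 10 for a comparison of 3 libraries with 3 and 100 drawn with a fixed seed for the results that use all groups. The overlap between comparisons that share libraries was set beside simulated data with no FHL2 effect, in which genes varied independently. No data were left out.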

Results

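Polyadenylated RNA was sequenced from 3T3-L1 cells, a mouse preadipocyte line that forms fat cells under hormonal induction and that the labels class as mesenchymal stem cells. The cells carried an FHL2-GFP construct or a control GFP construct. FHL2 is a LIM-domain protein that acts as a transcriptional cofactor, NFAT5 is the transcription factor of the response to high tonicity, and the title of the series places both in a complex of early adipogenesis. Cells were taken after confluence (day 0) and after 2 days with insulin, dexamethasone and isobutylmethylxanthine (day 2), which gave 4 groups of 3 libraries. Levels are CPM, as mean ± SD over the 3 libraries of a group. The labels do not say that these came from separate cultures, so each p measures only the spread between libraries. That spread is a single estimate per gene over all 12 libraries. The day 2 libraries varied more than the day 0 libraries (biological coefficient of variation 0.463 and 0.123).

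Fewer genes had a count at day 2, 12689 to 16131 per library, than at day 0, 17977 to 18811. The ranges were 12689 to 15831 and 17312 to 18022 after every library was thinned to the smallest total. Control replicate 3 (12689 genes) and FHL2 replicates 1 (13657 genes) and 2 (14158 genes), all of day 2, had the fewest. Mitochondrially encoded genes took 2.40% to 2.92% of the counts at day 2 and 3.43% to 4.38% at day 0. Genes of low GC content were lower at day 2. Of 5 classes by GC content, the lowest had a median log2 fold change from day 0 to day 2 of -1.66 in control and -1.54 in FHL2, and the highest had 0.77 and 0.74. Across the 10443 genes of known GC content with a mean of at least 5 CPM, which are not independent replicates, Spearman's rho between GC content and this change was 0.689 in control and 0.670 in FHL2. Between the lines it was 0.167 at day 0 and -0.0762 at day 2. Changes between the days are therefore given with the value after a correction for GC content where it ends a call or turns a direction.

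**Figure D1:**
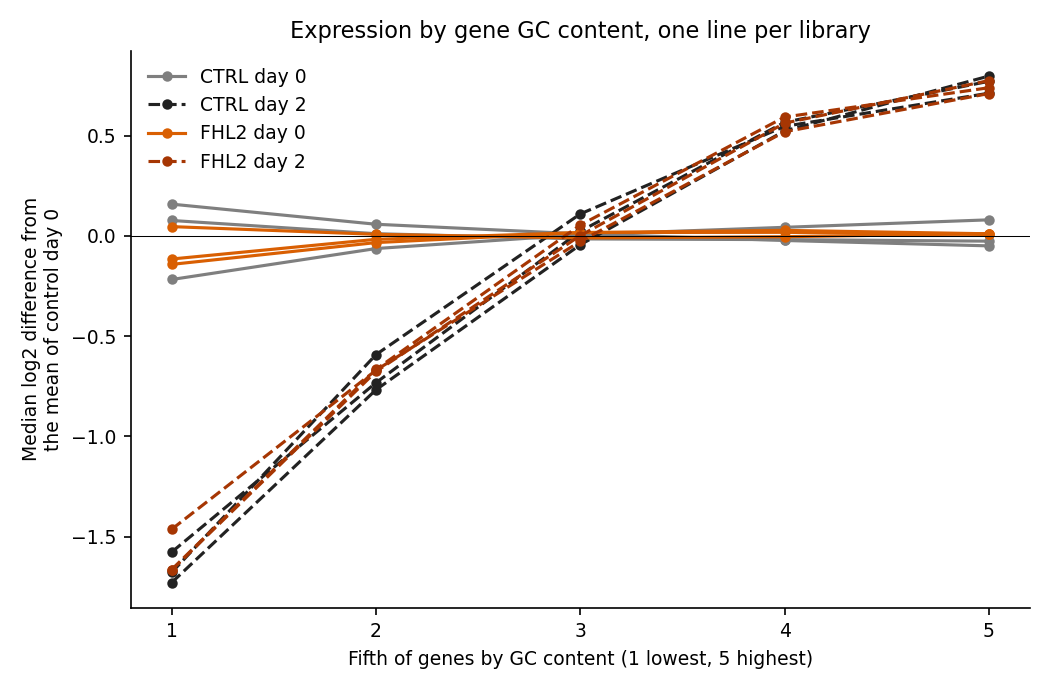
Median log2 difference from the mean of the control day 0 libraries (vertical axis) for the tested genes in each of 5 classes of GC content (horizontal axis), with 1 line per library. Day 2 libraries lie below day 0 libraries in the class with the lowest GC content and above them in the class with the highest, where the medians of the change with induction were -1.66 and 0.77 in control.

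Fhl2 (ENSMUSG00000008136), the gene named by the construct, was not called higher in the libraries labelled FHL2 with all libraries in the fit. Its level was 62.7 ± 4.35 against 61.2 ± 2.40 CPM at day 0 (log2 fold change 0.036, SE 0.23, adjusted p = 1.00). At day 2 it was 17.1 ± 6.49 against 16.3 ± 4.03 CPM (log2 fold change 0.075, SE 0.25, adjusted p = 0.914). Without the 3 day 2 libraries with the fewest genes, which leaves 1 FHL2 library at day 2, Fhl2 was called higher at day 2 (log2 fold change 0.66, adjusted p = 0.0206). Whether the transcript of the construct is counted at the mouse gene is not given in the sources used here, so the directions given for FHL2 follow the labels. Fhl2 fell from day 0 to day 2 by 1.91 on the log2 scale in control (adjusted p = 1.40e-05) and by 1.87 in FHL2 (adjusted p = 1.63e-05). Nfat5 (ENSMUSG00000003847) was measured at 531 ± 57.1 against 629 ± 106 CPM at day 0 (log2 fold change -0.25, SE 0.23, adjusted p = 1.00). At day 2 it had 203 ± 87.4 against 269.6 ± 41.4 CPM (log2 fold change -0.41, SE 0.24, adjusted p = 0.39), and neither difference passed the test. The day 2 difference of Nfat5 passed without a filter on low counts (log2 fold change -0.41, adjusted p = 0.00747) and without the 3 libraries with the fewest genes (-1.29, adjusted p = 0.00218). With induction Nfat5 fell by 1.22 on the log2 scale in control (adjusted p = 0.000526) and by 1.38 in FHL2 (adjusted p = 0.000201). After the correction for GC content the log2 changes of Nfat5 were 0.037 (adjusted p = 0.906) and -0.24 (adjusted p = 0.393), so neither call held. With transcript length added they were 0.50 (adjusted p = 0.00130), a call in the other direction, and 0.26 (adjusted p = 0.0581).

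**Figure D2:**
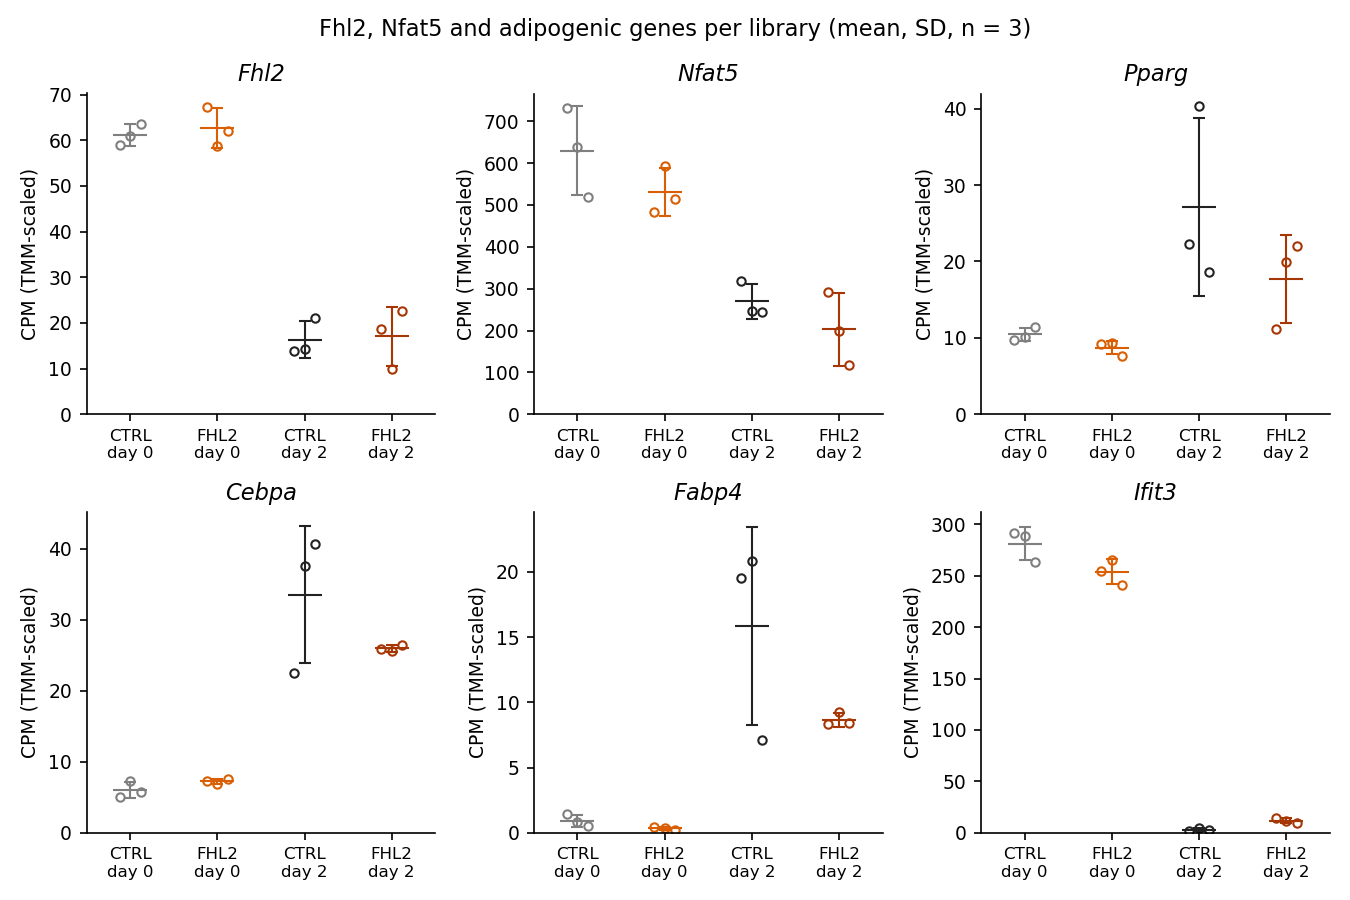
CPM on a linear scale (vertical axis) of Fhl2, Nfat5, Pparg, Cebpa, Fabp4 and Ifit3 in the 3 libraries of each group (points), with the mean and SD (bars). Fhl2 lies at similar levels in both lines at each day, 62.7 ± 4.35 and 61.2 ± 2.40 CPM at day 0, and Fabp4, Cebpa and Pparg lie higher at day 2 in both lines.

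Day 2 against day 0 in the control line compares cells after and before induction without the FHL2 construct. No uninduced group was taken at day 2, so time and any batch cannot be told apart from induction. Changes with induction are those from day 0 to day 2. Of 20 tested transcription factors of adipogenesis, 10 rose and 4 fell. Cebpd, which acts early, rose from 17.1 ± 3.24 to 293 ± 77.7 CPM (log2 fold change 4.1, SE 0.26, adjusted p = 1.64e-08). So did Cebpb, from 24.2 ± 2.02 to 140.3 ± 18.0 CPM (log2 fold change 2.54, SE 0.16, adjusted p = 2.41e-08). Cebpa and Pparg, which direct terminal differentiation, rose by 2.47 (SE 0.25, adjusted p = 1.15e-06) and 1.38 (SE 0.31, adjusted p = 0.00166) on the log2 scale, while Klf5 rose by 2.65 (SE 0.21, adjusted p = 1.35e-07). The counts of adipogenic transcription factors were the same when adjusted over the list alone (10 and 4), and the list passed camera (adjusted p = 0.000880, and adjusted p = 0.0262 with an estimated correlation). In a fit of the control libraries alone it did not pass with an estimated correlation (camera adjusted p = 0.0944). Nr3c1, the glucocorticoid receptor, was among the members that fell, by 2.57 on the log2 scale (adjusted p = 1.29e-05).

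Genes of lipid storage appeared in the control line with induction. Plin1, which coats lipid droplets, had no count at day 0 and 15.8 ± 2.71 CPM at day 2, at least 299-fold higher against the floor of 3 counts over the group. Cidec, a lipid droplet protein, was at least 277-fold higher, and Adipoq, the adipocyte hormone adiponectin, at least 73.8-fold higher (adjusted p = 0.00907, and 0.0502 with DESeq2). Fabp4, a fatty acid carrier, rose from 0.919 ± 0.458 to 15.9 ± 7.57 CPM (log2 fold change 4.08, SE 0.51, adjusted p = 1.04e-05). Among 24 mature adipocyte genes, 17 rose and 1 fell, also when adjusted over the list alone (17 and 1). The median log2 fold change was 1.59, the same with the 5 members without a count in a group placed at their bound, and 0.99 without those members. Camera gave an adjusted p = 0.000666, but the list did not pass at adjusted p = 0.237 with an estimated correlation. The preadipocyte marker Dlk1 had 6631 ± 916 against 6319.6 ± 492 CPM at day 2 against day 0 (log2 fold change 0.069, SE 0.089, adjusted p = 0.534), a difference that turned to -0.45 (adjusted p = 0.000813) after the correction for GC content. Of 18 preadipocyte and anti-adipogenic genes, 3 rose and 8 fell (3 and 8 when adjusted over the list alone, camera adjusted p = 0.869). Ly6a, a surface antigen of progenitors, rose by 1.69 (SE 0.14, adjusted p = 2.33e-07) on the log2 scale. Klf7 fell by 1.42 and Klf3 by 0.96 on the log2 scale, calls that were lost after the correction for GC content (log2 changes -0.65 and -0.28, adjusted p = 0.0509 and 0.190).

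Targets of the inducing hormones made up the list with the largest median rise among the lists tested in control. Among 20 glucocorticoid and cAMP response genes, 16 rose and 1 fell (17 and 1 when adjusted over the list alone). Their median log2 fold change was 2.94 (camera adjusted p = 9.14e-34, and adjusted p = 1.81e-05 with an estimated correlation). Zbtb16, a glucocorticoid-induced zinc finger factor, rose from 0.122 ± 0.0139 to 28.2 ± 1.49 CPM (adjusted p = 4.15e-08). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 23.2 ± 1.72 to 327 ± 37.2 CPM (adjusted p = 1.56e-11), and the secreted lipocalin Lcn2 from 0.327 ± 0.245 to 129 ± 16.2 CPM (adjusted p = 6.00e-11). Retnla, a secreted resistin-like protein, and Ear2, a ribonuclease with near-identical copies to which reads cannot be assigned with certainty, had no count at day 0 and were at least 765-fold and 688-fold higher at day 2.

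Interferon-stimulated genes, which encode antiviral proteins, fell together. Of 27, 26 fell and 0 rose, as when adjusted over the list alone (26 and 0). Their median log2 fold change was -2.92 (camera adjusted p = 1.71e-26, and adjusted p = 0.00263 with an estimated correlation). In a fit of the control libraries alone the list did not pass with an estimated correlation (camera adjusted p = 0.0573). Ifit3 fell from 281 ± 16 to 3.15 ± 1.47 CPM (log2 fold change -6.48, SE 0.25, adjusted p = 1.84e-10). Ifit2 fell by 6.45 and Ifit3b, a near copy of Ifit3, fell by 6.27 on the log2 scale. Rsad2 had 44.3 ± 4.1 CPM at day 0 and 0.0490 ± 0.0849 CPM at day 2, the latter from 2 counts in all (adjusted p = 2.61e-07). Nexn, an actin-binding protein, was among the largest falls, from 21.9 ± 8.26 to 0.244 ± 0.363 CPM (adjusted p = 0.000216). Of 22 actin cytoskeleton and SRF targets, 6 rose and 10 fell, also when adjusted over the list alone (6 and 10). Camera gave an adjusted p = 0.0445 for them (adjusted p = 0.237 with an estimated correlation, which was 0.00317 after the correction for GC content). The call was lost without control day 0 replicate 3 (0.0749) and without day 2 replicates 1, 2 and 3 (0.0575, 0.0508 and 0.0749).

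Genes of the tonicity response passed as a list only after the correction for GC content. Of 14 tested NFAT5 and tonicity response genes, 4 rose and 3 fell (4 and 3 when adjusted over the list alone, camera adjusted p = 0.113). With the correction 6 rose and 0 fell (6 and 1 when adjusted over the list alone), and the list passed upward (adjusted p = 0.00268, and adjusted p = 0.0330 with an estimated correlation). The water channel Aqp1 rose by 2.01 (SE 0.091, adjusted p = 8.32e-10) on the log2 scale and the aldose reductase Akr1b3 by 1.10 (SE 0.19, adjusted p = 0.000168). The inositol carrier Slc5a3 fell by 1.36 and the chaperone Hspa4l by 2.53 on the log2 scale (adjusted p = 0.000184 and 7.47e-05). Neither call held after the correction for GC content (log2 changes 0.12 and -0.69, adjusted p = 0.658 and 0.126). Before this correction 12 of 29 S phase genes rose and 5 fell (12 and 5 when adjusted over the list alone, camera adjusted p = 0.118). After it 14 rose and 0 fell (14 and 0 when adjusted over the list alone, adjusted p = 0.0143, but adjusted p = 0.275 with an estimated correlation). Of 26 genes of G2 and mitosis 10 rose and 9 fell (10 and 9 when adjusted over the list alone, adjusted p = 0.929). Pold1, a subunit of a replicative polymerase, rose by 1.67 (SE 0.22, adjusted p = 1.53e-05) on the log2 scale, and Nusap1, a spindle protein, fell by 2.44 (adjusted p = 7.09e-05). Pola1, Prim1, Bub1, Cenpf and the proliferation marker Mki67 fell by 2.25, by 1.56, by 2.34, by 2.50 and by 1.30 on the log2 scale. These calls all ended after the correction for GC content (log2 changes -0.70, -0.55, -0.78, -1.33 and -0.78, with adjusted p from 0.0503 to 0.235). Cenpf also lost its call without control day 0 replicate 1 or 2 or day 2 replicate 1 (adjusted p = 0.0565, 0.0661 and 0.0710).

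The remaining lists did not pass camera in control before the correction for GC content. Collagens and extracellular matrix genes rose in 12 and fell in 13 of 32 cases (13 and 13 when adjusted over the list alone, camera adjusted p = 0.980). Col1a1, the main collagen of these lists, fell by 0.96 on the log2 scale (adjusted p = 2.79e-07). YAP and TEAD targets had 1 rise and 11 falls of 19 (0.0963), cholesterol biosynthesis 3 and 11 of 22 (0.0641), and p53 targets 3 and 7 of 16 (0.136). Inflammatory genes had 7 and 7 of 21 (0.153), and all of these counts were the same adjusted over the list alone. After the correction these 4 lists passed in the same directions (adjusted p = 0.000287 for YAP and TEAD targets, 0.00675 for cholesterol biosynthesis, 0.0113 for p53 targets and 0.00675 for inflammatory genes). In the same order they had adjusted p = 0.0366, 0.0914, 0.0852 and 0.0357 with an estimated correlation. Matrix proteases had 8 rises and 7 falls of 21 (0.869), stress response genes 5 and 6 of 20 (0.953), circadian clock genes 4 and 6 of 16 (0.488). Wnt targets had 2 and 2 of 8 (0.953), again with all counts the same adjusted over the list alone. Bone and cartilage markers had 1 rise and 2 falls of 6 (0.413) and endothelial markers 0 and 0 of 6 (0.929). Mitochondrially encoded genes had 6 falls and 0 rises of 10 and leaned down relative to other genes (0.249), a direction that turned up after the correction for GC content (adjusted p = 1.41e-11, and adjusted p = 0.0165 with an estimated correlation). Too few members were tested of the markers of muscle (2), of macrophages and blood (4) and of epithelium (1), and of the FHL family, a list that leaves out Fhl2 (3). Of these 0, 1, 0 and 1 rose and none fell. In all, 3799 genes rose and 4447 fell in control, 5096 of them at least 2-fold. After the correction for GC content 5769 were called, 4555 of them shared and 4282 in the same direction, and 12 lists rather than 5 passed camera.

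The same comparison in the FHL2 line asks whether induction proceeds with the FHL2 construct. Cebpd rose from 26.2 ± 4.36 to 209 ± 61.1 CPM (log2 fold change 3.00, SE 0.24, adjusted p = 1.85e-07), and Cebpb and Cebpa rose by 2.13 (SE 0.16, adjusted p = 1.16e-07) and 1.84 (SE 0.24, adjusted p = 1.49e-05) on the log2 scale. Pparg rose by 1.02 (SE 0.31, adjusted p = 0.0118), a call lost without FHL2 day 0 replicate 3 (adjusted p = 0.0507) and without day 2 replicate 3 (0.0517), and with the correction for GC content and length (0.0533). Klf5 rose by 2.44 (SE 0.21, adjusted p = 2.90e-07). Fabp4 rose from 0.334 ± 0.0929 to 8.67 ± 0.528 CPM (adjusted p = 5.76e-06), and the lipase Lipe by 2.96 (SE 0.16, adjusted p = 6.52e-09) on the log2 scale. Plin1 was at 4.16 ± 1.72 CPM at day 2, at least 90.4-fold higher than at day 0, where it had no count. Adipoq, also without a count at day 0, was at least 17.5-fold higher (adjusted p = 0.0299). Its call was lost without FHL2 day 0 replicate 1, 2 or 3 (0.0710, 0.0685 and 0.0694) and with DESeq2 (0.147) or limma-voom (0.205). The fatty acid synthase Fasn rose by 1.53 (SE 0.13, adjusted p = 4.31e-07) on the log2 scale, and Elovl6, which lengthens fatty acids, fell by 1.61 (adjusted p = 2.08e-05, and 0.0892 at -0.43 after the correction for GC content and length).

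Of the adipogenic transcription factors in FHL2, 10 rose and 6 fell of 20 (10 and 7 when adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.0780 with an estimated correlation). Mature adipocyte genes rose in 11 and fell in 2 of 24 cases, the same when adjusted over the list alone (11 and 2). By camera the list had adjusted p = 0.0228 and adjusted p = 0.343 with an estimated correlation. Their median log2 fold change was 1.32, and 0.55 without the 5 members that had no count in a group. Glucocorticoid and cAMP response genes rose in 17 and fell in 1 of 20 cases, also when adjusted over the list alone (17 and 1). Camera gave them adjusted p = 9.73e-32 and adjusted p = 2.30e-05 with an estimated correlation. Zbtb16 rose by 7.25 (SE 0.51, adjusted p = 6.02e-08), Lcn2 by 7.60 (SE 0.25, adjusted p = 6.94e-11) and Fkbp5 by 4.07 (SE 0.11, adjusted p = 1.90e-11) on the log2 scale. Interferon-stimulated genes fell in 26 of 27 cases, also when adjusted over the list alone (26). Their median log2 fold change was -1.85 (camera adjusted p = 3.36e-17, and adjusted p = 0.0384 with an estimated correlation). Rsad2 went from 33.9 ± 0.809 to 0.543 ± 0.741 CPM (adjusted p = 1.13e-06) and Ifit3 from 254 ± 12.1 to 11.8 ± 2.40 CPM (adjusted p = 1.55e-09).

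Actin cytoskeleton and SRF targets had 3 rises and 11 falls of 22 in FHL2 (4 and 11 when adjusted over the list alone, adjusted p = 0.0137, but adjusted p = 0.152 with an estimated correlation). YAP and TEAD targets had 1 rise and 12 falls of 19, as when adjusted over the list alone (1 and 12). Camera gave these adjusted p = 0.0244 and adjusted p = 0.196 with an estimated correlation. Inflammatory genes had 8 rises and 5 falls of 21 (9 and 5 when adjusted over the list alone, adjusted p = 0.0424, and adjusted p = 0.164 with an estimated correlation). NFAT5 and tonicity response genes rose in 6 and fell in 4 of 14 cases, also when adjusted over the list alone (6 and 4, camera adjusted p = 0.0716). After the correction for GC content 6 rose and 3 fell, and the list passed upward (adjusted p = 0.00150, and adjusted p = 0.0209 with an estimated correlation). Aqp1 rose by 2.04 (SE 0.091, adjusted p = 9.09e-10) and Akr1b3 by 0.99 (SE 0.19, adjusted p = 0.000428) on the log2 scale. Slc5a3 fell by 1.47 on the log2 scale (adjusted p = 9.29e-05), a call lost after the correction for GC content (log2 change -0.13, adjusted p = 0.632). The replication genes Mcm5 and Tk1 rose by 1.78 (SE 0.11, adjusted p = 2.22e-08) and 1.53 (SE 0.25, adjusted p = 0.000137). In all, 15 of 29 S phase genes rose and 6 fell (15 and 6 when adjusted over the list alone, adjusted p = 0.0797). After the correction for GC content the S phase list passed (14 and 2, adjusted p = 0.0112, but adjusted p = 0.258 with an estimated correlation). So did G2 and mitosis upward and collagens and extracellular matrix downward (adjusted p = 0.0184 and 0.000805, but adjusted p = 0.292 and 0.358 with an estimated correlation), and mitochondrially encoded genes upward (adjusted p = 6.11e-09, and 0.0209 with an estimated correlation). The actin, YAP and inflammatory lists then also passed with an estimated correlation (adjusted p = 0.00269, 0.0209 and 0.0191).

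The following genes were among the largest changes in FHL2 by rule. Retnla and haptoglobin, Hp, had no count at day 0 and were at least 1499-fold and 821-fold higher at day 2. Ear2 rose from 0.0326 ± 0.0564 CPM (2 counts) to 50.2 ± 4.34 CPM (adjusted p = 5.65e-09). Cyp2f2, a cytochrome P450, rose from 0.0475 ± 0.0822 CPM (3 counts) to 17.5 ± 3.41 CPM (adjusted p = 8.07e-07). Prex2, a Rac exchange factor, had 14.4 ± 1.20 CPM at day 0 and no count at day 2, at least 217-fold lower. Smarca1, a chromatin remodeller, Adamts6 and Mterf2 fell by 6.03, by 5.53 and by 5.34 on the log2 scale. In all, 3730 genes rose and 4357 fell. After the correction for GC content 5783 were called, 4318 of 4574 shared genes in the same direction. Both lines shared 6960 genes called in the same direction, where independent lists would share 2324. In opposite directions 2 genes were called. Across genes, which are not independent replicates, the changes in both lines had a Pearson's r of 0.944, and simulated data without an FHL2 effect gave 0.938 to 0.945.

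FHL2 against control at day 0 asks what the construct changes before induction. Sod3, the extracellular superoxide dismutase, was higher in FHL2 at 447 ± 12.5 against 249 ± 13.6 CPM (log2 fold change 0.84, SE 0.080, adjusted p = 0.000672). So was Thy1, a surface glycoprotein of fibroblasts and preadipocytes, at 295 ± 8.86 against 199 ± 9.59 CPM (log2 fold change 0.56, SE 0.078, adjusted p = 0.010). Spon2, a secreted matrix protein, was lower at 14.4 ± 1.66 against 32.2 ± 1.17 CPM (log2 fold change -1.15, SE 0.13, adjusted p = 0.00354). The gelatinase Mmp9 was lower at 60.8 ± 2.76 against 100.3 ± 6.28 CPM (log2 fold change -0.72, SE 0.11, adjusted p = 0.0356). Adamts2, which trims procollagen, was lower at 44.2 ± 0.555 against 72.1 ± 5.38 CPM (log2 fold change -0.70, SE 0.10, adjusted p = 0.010). Lrig1, a membrane protein that restrains growth factor receptors, was lower at 28.5 ± 2.65 against 52.7 ± 1.00 CPM (log2 fold change -0.89, SE 0.12, adjusted p = 0.00944). The seventh call, named although its symbol falls outside the rule, was the pseudogene Gm5886 at 261 ± 30.6 against 105 ± 9.77 CPM (log2 fold change 1.31, SE 0.17, adjusted p = 0.00760), whose reads cannot be assigned with certainty among related genes. The libraries of both lines did not overlap in any of these 7 genes.

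Adipogenic transcription factors were not called at day 0 with all libraries in the fit. Pparg had 8.71 ± 0.888 against 10.4 ± 0.903 CPM (log2 fold change -0.26, SE 0.31, adjusted p = 1.00) and Cebpd 26.2 ± 4.36 against 17.1 ± 3.24 CPM (log2 fold change 0.62, SE 0.24, adjusted p = 0.932). By edgeR 0 of 20 adipogenic transcription factors were called in the fit of all libraries, also when adjusted over the list alone. A fit of the day 0 libraries alone called 1 (3 when adjusted over the list alone), and a fit without a filter on low counts called Cebpd (adjusted p = 0.00439). Of 14 NFAT5 and tonicity response genes 0 were higher and 0 lower (0 and 1 when adjusted over the list alone, adjusted p = 0.876). Slc5a3 had 254 ± 10.1 against 212 ± 37.4 CPM (adjusted p = 1.00). Small shifts of whole lists passed camera at its preset correlation, and none passed with an estimated correlation. Mitochondrially encoded genes passed upward only after the correction for GC content (adjusted p = 2.42e-05, but adjusted p = 0.0882 with an estimated correlation). Cholesterol biosynthesis genes leaned lower in FHL2, with a median log2 fold change of -0.22 over 22 genes, 0 of them called (0 when adjusted over the list alone). Camera gave adjusted p = 0.000229 and adjusted p = 0.0738 with an estimated correlation. Preadipocyte and anti-adipogenic genes leaned higher, with 1 of 18 called, Thy1 (2 higher and 1 lower when adjusted over the list alone). The list had a camera adjusted p = 0.0150, and adjusted p = 0.0738 with an estimated correlation. Matrix proteases and inhibitors leaned lower, with 2 of 21 called, Mmp9 and Adamts2 (1 higher and 5 lower when adjusted over the list alone). Camera gave adjusted p = 0.0150, and adjusted p = 0.0738 with an estimated correlation. Inflammatory genes (0 of 21 called, 1 lower when adjusted over the list alone) leaned lower at 0.0240 and adjusted p = 0.126 with an estimated correlation. Interferon-stimulated genes (0 of 27 called, also adjusted over the list alone) leaned lower at 0.0234 and adjusted p = 0.457 with an estimated correlation. The matrix protease call was lost without control replicate 3 (0.102) and FHL2 replicate 1 (0.0607). So was the inflammatory call (0.103 and 0.0514), and the interferon call without FHL2 replicate 3 (0.0985).

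In all, 3 genes were higher and 4 lower in FHL2 at day 0, and 600 had an unadjusted p under 0.05. Sod3 kept its call on leaving out each of the 6 libraries. The number of calls was 4, 3 and 3 without control replicates 1, 2 and 3, and 5, 3 and 1 without FHL2 replicates 1, 2 and 3. A fit of the day 0 libraries alone, whose spread is smaller, called 246 genes, among them all 7, and DESeq2 called 93.

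At day 2, 6 of 27 interferon-stimulated genes were higher in FHL2 than in control, and 4 of 20 glucocorticoid and cAMP response genes were lower. Both lists passed camera also with an estimated correlation (adjusted p = 0.0277 and 0.0277), while mature adipocyte genes and matrix genes leaned lower and did not (adjusted p = 0.0501 and 0.310). A fit of the day 2 libraries alone, whose spread is larger, called 0 of 24 interferon-stimulated genes and 1 of 20 glucocorticoid and cAMP response genes (7 and 7 when adjusted over the list alone). Interferon-stimulated genes had 6 higher and 0 lower (14 and 0 when adjusted over the list alone), with a median log2 fold change of 0.58. Ifit3 had 11.8 ± 2.40 against 3.15 ± 1.47 CPM (log2 fold change 1.90, SE 0.24, adjusted p = 0.00202) and Mx1 7.10 ± 1.61 against 3.54 ± 0.280 CPM (log2 fold change 1.01, SE 0.20, adjusted p = 0.0198). Gbp2, a guanylate-binding protein with related copies, had 30.7 ± 5.70 against 15.4 ± 4.53 CPM (log2 fold change 0.99, SE 0.19, adjusted p = 0.0161). With the day 2 libraries alone Ifit3, Mx1 and Gbp2 had adjusted p = 0.164, 0.656 and 0.221. The list passed camera (adjusted p = 6.21e-15, and adjusted p = 0.0277 with an estimated correlation). In a fit of the day 2 libraries alone it had adjusted p = 0.195 with an estimated correlation. Mature adipocyte genes had a median log2 fold change of -0.73 over 24 genes, with 1 called lower and 0 higher (7 and 0 when adjusted over the list alone). By camera it had adjusted p = 2.18e-07 and adjusted p = 0.0501 with an estimated correlation, which was 0.0450 after the correction for GC content. In a fit of the day 2 libraries alone it was 0.161, with 0 of 22 genes called lower (8 when adjusted over the list alone). The called member was Plin4, a lipid droplet protein, at 21.6 ± 3.86 against 46.7 ± 9.24 CPM (log2 fold change -1.11, SE 0.20, adjusted p = 0.0117), with adjusted p = 0.0910 in that fit. Plin1 had 4.16 ± 1.72 against 15.8 ± 2.71 CPM (log2 fold change -1.92, SE 0.48, adjusted p = 0.0777) and was called lower by DESeq2 (0.00287), by limma-voom (0.00504), without a filter on low counts (0.0278) and without the 3 libraries with the fewest genes (0.0211). Fabp4 had 8.67 ± 0.528 against 15.9 ± 7.57 CPM (log2 fold change -0.87, SE 0.45, adjusted p = 0.322). Adipogenic transcription factors had 0 and 0 calls of 20, also when adjusted over the list alone (0 and 0, adjusted p = 0.0814). Pparg had a log2 fold change of -0.62 (adjusted p = 0.308) and Cebpa of -0.37 (adjusted p = 0.427). Cebpb had -0.53 (SE 0.15, adjusted p = 0.0954) and was called lower by DESeq2 (adjusted p = 0.0195), without a filter on low counts (0.0269) and without FHL2 replicate 3 (0.0373).

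Of 32 collagens and extracellular matrix genes 7 were lower and 1 higher in FHL2 at day 2 (12 and 1 when adjusted over the list alone). The list had a camera adjusted p = 5.11e-05, but adjusted p = 0.310 with an estimated correlation. Tnc, the matrix glycoprotein tenascin C, had 185 ± 22.4 against 359 ± 59.7 CPM (log2 fold change -0.96, SE 0.12, adjusted p = 0.00165). Fbn1, a microfibril protein, had 162 ± 20.6 against 277 ± 18.1 CPM (log2 fold change -0.77, SE 0.13, adjusted p = 0.00719), and Col15a1 6.24 ± 2.83 against 20.7 ± 3.58 CPM (log2 fold change -1.73, SE 0.36, adjusted p = 0.0251). Col1a1 was lower at -0.40 (SE 0.081, adjusted p = 0.0226, and 0.161 with the day 2 libraries alone). Of 21 matrix proteases and inhibitors 4 were lower and 2 higher (6 and 2 when adjusted over the list alone, adjusted p = 0.0170, and adjusted p = 0.0912 with an estimated correlation). Adamts4 had a log2 fold change of -1.29, Adamts12 of -0.79 and the protease inhibitor Serpine2 of 0.69 (adjusted p = 0.0210, 0.0442 and 0.00889). Wnt targets had a median of -0.58 over 8 genes with 0 called, also when adjusted over the list alone (0, adjusted p = 0.0170, and adjusted p = 0.193 with an estimated correlation). The matrix call was lost without control replicate 1 (0.0621), and the protease call without control replicate 1 (0.0969) and FHL2 replicate 3 (0.0869). The Wnt call was lost without control replicates 1 and 2 (0.105 and 0.191) and FHL2 replicate 2 (0.122).

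Glucocorticoid and cAMP response genes were lower in 4 and higher in 0 of 20 cases (6 and 0 when adjusted over the list alone). Camera gave adjusted p = 6.86e-05 and adjusted p = 0.0277 with an estimated correlation, which was 0.11 in a fit of the day 2 libraries alone. They included the metallothionein Mt2 at 152 ± 8.98 against 249 ± 17.8 CPM (log2 fold change -0.71, SE 0.11, adjusted p = 0.00540) and the nuclear receptor Nr4a1 at 90.9 ± 13.7 against 142 ± 9.94 CPM (log2 fold change -0.65, SE 0.15, adjusted p = 0.0369). Angptl4, an inhibitor of lipoprotein lipase, had 351 ± 12.4 against 507 ± 19.0 CPM (log2 fold change -0.53, SE 0.085, adjusted p = 0.00653). Nr4a1 lost its call without any 1 library but FHL2 replicate 3 (adjusted p up to 0.113). It was also lost with the day 2 libraries alone (0.115). Angptl4 had adjusted p = 0.0675 in that last fit. Genes of G2 and mitosis leaned higher, with a median of 0.37 over 26 genes and 0 called (5 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00295, but adjusted p = 0.269 with an estimated correlation). Stress response genes were higher in 2 and lower in 0 of 20 cases (3 and 0 when adjusted over the list alone, adjusted p = 0.0170, and adjusted p = 0.269 with an estimated correlation). They were Ddit3, the stress factor CHOP, at 0.53 and Phgdh, which starts serine synthesis, at 0.55 (adjusted p = 0.0415 and 0.0419). Ddit3 lost its call with upper-quartile scaling, the replicate block, both corrections for GC content and the day 2 libraries alone (adjusted p = 0.374). The call was also lost without control replicates 1 or 2 and FHL2 replicates 2 or 3 (up to 0.0912). Phgdh lost its call with upper-quartile scaling (adjusted p = 0.0531) and the day 2 libraries alone (0.257). On leaving out 1 library it held only without FHL2 replicate 1, with adjusted p up to 0.122 otherwise. The G2 call was lost without control replicate 3 (0.0533), the library with the fewest genes. The stress call was lost without control replicate 1 (0.111), FHL2 replicate 2 (0.115) and FHL2 replicate 3 (0.0936), and with the correction for GC content and length (0.150).

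Of 14 NFAT5 and tonicity response genes 1 was lower and 0 higher (1 and 1 when adjusted over the list alone, adjusted p = 0.742). The lower gene was the amino acid carrier Slc38a2 at 85.0 ± 11.5 against 133 ± 8.06 CPM (log2 fold change -0.64, SE 0.10, adjusted p = 0.00653). Akr1b3 had -0.082 (adjusted p = 0.864) and the taurine carrier Slc6a6 -0.26 (adjusted p = 0.174). Preadipocyte genes were higher in 3 of 18 cases (3 when adjusted over the list alone, adjusted p = 0.641), Thy1 at 0.40, Ly6a at 0.62 and Ddit3. Acta2, the smooth muscle actin, was 1 of 2 higher genes of 22 actin genes (log2 fold change 0.70, SE 0.15, adjusted p = 0.0292, list adjusted p = 0.742). The clock repressors Nr1d1 and Bhlhe40 moved apart, at 0.91 (SE 0.18, adjusted p = 0.0216) and -0.79 (SE 0.18, adjusted p = 0.0358). The call of Nr1d1 was lost without control replicates 2 or 3 and FHL2 replicates 1 or 2 (adjusted p up to 0.0769). That of Bhlhe40 was lost without control replicates 1 or 2 and FHL2 replicates 1 or 3 (up to 0.111). With the day 2 libraries alone Nr1d1 and Bhlhe40 had 0.123 and 0.206. The inflammatory brake Tnfaip3 had -1.47 (SE 0.34, adjusted p = 0.0419) and the endothelial receptor Flt1 -0.91 (SE 0.21, adjusted p = 0.0388). The calls of Tnfaip3 and Flt1 were lost with the replicate block (adjusted p = 0.0796 and 0.0703) and with the day 2 libraries alone (0.359 and 0.388). They were also lost without control replicates 1 or 2 or FHL2 replicate 2 (adjusted p up to 0.125). Of 4 macrophage and blood, 1 epithelial and 2 muscle markers and 3 FHL family genes, 0 were called.

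Among the 5 largest falls by rule was that of Tgm2, a protein crosslinking enzyme, at 0.303 ± 0.524 against 14.7 ± 1.78 CPM (log2 fold change -5.50, SE 0.86, adjusted p = 0.00635). Renin, Ren1, of which some strains carry a further copy, was also among them, at 6.98 ± 1.77 against 30.2 ± 8.58 CPM (log2 fold change -2.11, SE 0.36, adjusted p = 0.0103). Grem1, a BMP antagonist, was lower at -2.19 (SE 0.26, adjusted p = 0.000913), the calcium pump Atp2b4 at -2.07 (SE 0.43, adjusted p = 0.0267) and Emb, a membrane glycoprotein, at -1.89 (SE 0.28, adjusted p = 0.00521). Among the 5 largest rises by rule were Ifit3 and the angiotensin receptor Agtr2, the latter at 74.2 ± 17.1 against 30.8 ± 7.08 CPM (log2 fold change 1.27, SE 0.27, adjusted p = 0.0293). Wfdc3 was higher at 1.46 (SE 0.24, adjusted p = 0.00897), Pawr at 1.67 (SE 0.39, adjusted p = 0.0426) and Tubb3, a tubulin, at 1.81 (SE 0.42, adjusted p = 0.0424). The call of Pawr was lost without any 1 of 5 of the 6 day 2 libraries, and its log2 fold change was 0.56 (adjusted p = 0.174) without the 3 libraries with the fewest genes. Tubb3 was lost without any 1 of 5 of the 6 libraries, with adjusted p up to 0.101. With limma-voom the calls of Pawr, Mx1, Tnfaip3 and Gapdh ended (adjusted p = 0.150, 0.247, 0.0741 and 0.0506). In all, 104 genes were higher and 195 lower in FHL2, 86 of them at least 2-fold. A fit of the day 2 libraries alone called 39, of which 38 were shared. Among these were 17 of the 45 called genes named for this day, Tgm2, Ren1, Emb, Agtr2, Wfdc3, Tnc, Fbn1 and Mt2 among them. The call of Agtr2 was lost without control replicates 1 or 3 (adjusted p = 0.0826 and 0.0723), without FHL2 replicates 1 or 3 (0.0694 and 0.0541), with the replicate block (0.0528) and with the correction for GC content and length (0.0509). That of Ren1 was lost without control replicate 2 (0.0503). The calls of Acta2, Adamts4, Adamts12, Atp2b4, Col1a1, Col15a1, Gbp2, Ly6a, Mx1, Spon2 and Thy1 were also lost without some single library. All of them were lost with the day 2 libraries alone, as were Grem1, Serpine2 and Slc38a2. Without control replicate 1 there were 197 calls and without FHL2 replicate 2 there were 146, each without 17 of the 45 named. Leaving out control replicates 2 or 3 or FHL2 replicates 1 or 3 took away 15, 10, 10 and 13 of the 45. The replicate block took away 6 and the correction for GC content and length 8. Some of the 45 belong to lists chosen after the values were seen.

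**Figure D3:**
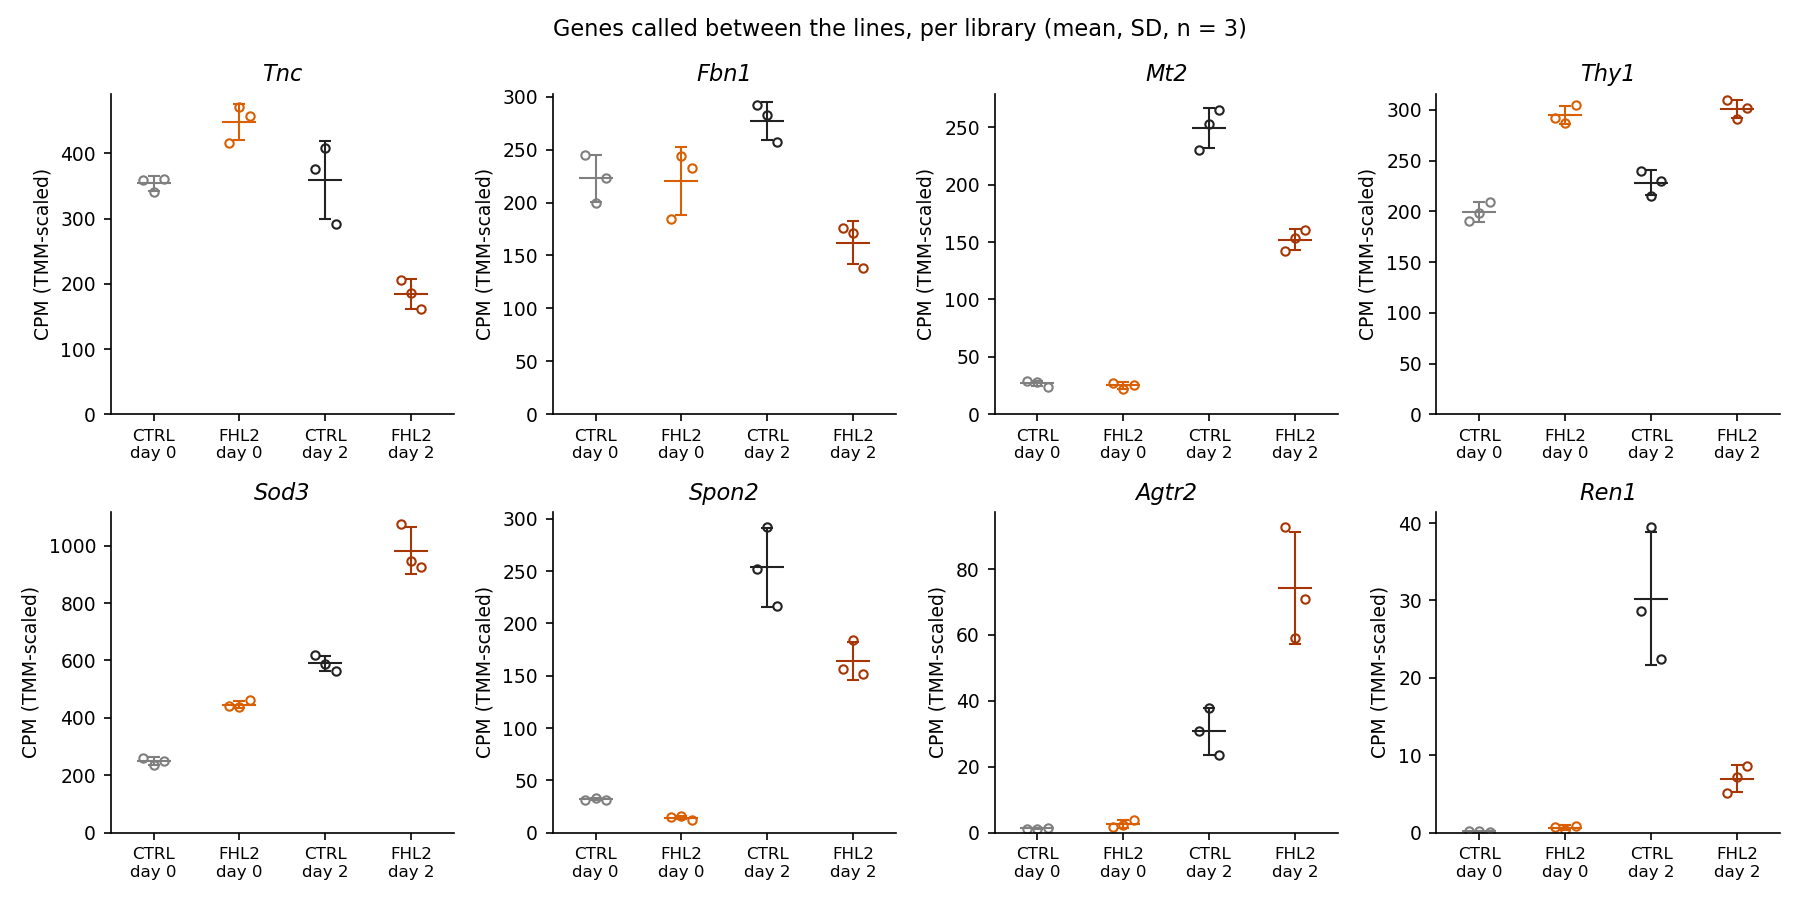
CPM on a linear scale (vertical axis) of Tnc, Fbn1, Mt2, Thy1, Sod3, Spon2, Agtr2 and Ren1 in the 3 libraries of each group (points), with the mean and SD (bars). Thy1 and Sod3 lie higher and Spon2 lower in FHL2 at both days, and Tnc lies lower in FHL2 at day 2, 185 ± 22.4 against 359 ± 59.7 CPM.

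**Figure D4:**
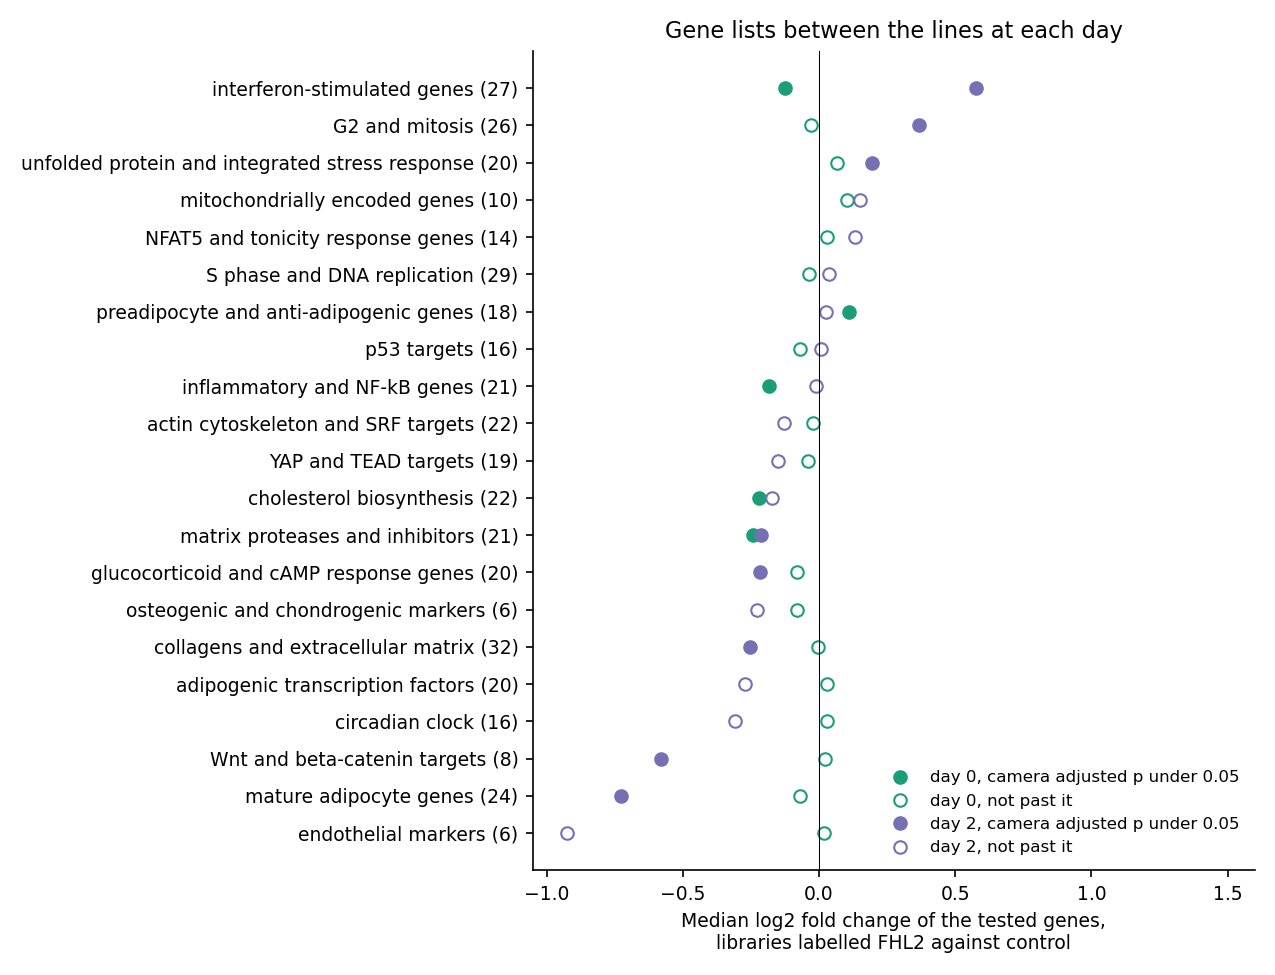
Median log2 fold change of FHL2 against control (horizontal axis) over the tested genes of each list (vertical axis) at day 0 and at day 2, with filled points where camera gave an adjusted p under 0.05 at its preset correlation. Interferon-stimulated genes lie at -0.13 at day 0 and 0.58 at day 2, and mature adipocyte genes at -0.070 and -0.73.

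Differences between the lines at both days were partly shared. Sod3, Thy1 and Gm5886 were higher and Spon2, Lrig1 and Adamts2 lower at both days. Their log2 fold changes at day 2 were 0.74, 0.40, 1.13, -0.63, -1.04 and -0.59, while Mmp9 had -0.35 (adjusted p = 0.127). These 6 genes compare with 0.0756 for independent lists. The comparisons share no library but use the same estimate of spread, so the lists need not be independent. In a fit of the day 2 libraries alone the day 2 calls of Thy1, Spon2 and Adamts2 were lost. Of the 299 genes called at day 2, 254 (84.9%) had the same sign at day 0. Across 10454 genes with a mean of at least 5 CPM, which are not independent replicates, Pearson's r between the differences at both days was 0.257, and simulated data without an FHL2 effect gave -0.016 to 0.018. Across all tested genes r was 0.136. Simulated genes varied independently, so the simulated range may be too narrow for genes that vary together, and no conclusion is drawn from it. Leaving out 1 library left between 1 and 7 shared genes, with fewer than 4 without control day 0 replicates 2 or 3 (3 and 2 genes) and FHL2 day 0 replicates 2 or 3 (3 and 1 genes).

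Genes that changed from day 0 to day 2 in control were set beside the difference between the lines at day 2, to see whether FHL2 cells reach other levels of them. Of the genes induced in control, 109 were lower and 35 higher in FHL2 at day 2, among the lower Angptl4 and Mt2. Independent lists would give 51.3 and 27.4. Of the genes that fell in control, 56 were higher, Ifit3 and Mx1 among them, and 43 lower. Independent lists would give 32.0 and 60.1. In simulated data without an FHL2 effect 0 to 3 induced genes were called lower and 0 to 26 repressed genes higher. Simulated genes varied independently, so such counts may spread more widely where genes vary together. Both comparisons use the control libraries of day 2, so the counts are not independent. Pearson's r of the changes across genes, -0.167, lay within the simulated -0.220 to -0.121. Opposite changes numbered 165, against 30 in fits of only the groups compared. They numbered 98 and 99 without control day 0 replicates 1 and 2, 102, 96 and 91 without FHL2 day 0 replicates 1, 2 and 3, and 89 without FHL2 day 2 replicate 2.

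The interaction tests whether a gene changed differently from day 0 to day 2 in both lines. The matrix glycoprotein gene Tnc passed. Its level was 448 ± 28.1 against 354 ± 11.3 CPM in FHL2 and control at day 0 (adjusted p = 0.773, and 0.0261 in a fit of the day 0 libraries alone) and 185 ± 22.4 against 359 ± 59.7 CPM at day 2 (adjusted p = 0.00165). It fell with induction by 1.28 on the log2 scale in FHL2 (adjusted p = 7.45e-07) and had a log2 change of 0.019 in control (adjusted p = 0.904), which was -0.40 (adjusted p = 0.0143) after the correction for GC content. The interaction of Tnc was -1.30 (SE 0.17, adjusted p = 0.0276). Interferon-stimulated genes, which fell with induction in both lines, fell less in FHL2, with a median interaction of 0.68 over 27 genes, 0 called (12 when adjusted over the list alone). The camera test gave adjusted p = 2.73e-23 and adjusted p = 0.0151 with an estimated correlation. Adipogenic transcription factors, mature adipocyte genes and glucocorticoid and cAMP response genes leaned lower, with medians of -0.23, -0.45 (-0.20 without the 5 members that had no count in a group) and -0.18. They had 0 called members, and 0, 2 and 3 when adjusted over the list alone. Camera gave adjusted p = 0.00837, 0.00731 and 0.00731 for these lists, and adjusted p = 0.0745, 0.255 and 0.0745 with an estimated correlation. The adipogenic call was lost without FHL2 day 2 replicate 3 (0.0765), and the mature adipocyte call without FHL2 day 2 replicates 1 and 3 (0.0681 and 0.0744).

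Collagens and extracellular matrix genes also leaned lower in the interaction (median -0.16, 1 of 32 called, 2 when adjusted over the list alone, adjusted p = 3.03e-05, but adjusted p = 0.335 with an estimated correlation). So did Wnt targets (median -0.44, adjusted p = 0.0253, and adjusted p = 0.255 with an estimated correlation) and endothelial markers (median -1.08, adjusted p = 0.0423, and adjusted p = 0.204 with an estimated correlation). Genes of G2 and mitosis leaned higher (median 0.27, adjusted p = 0.0143, and adjusted p = 0.360 with an estimated correlation). None of the last 3 lists had a called member, also when adjusted over the list alone. The G2 call was lost without control day 0 replicate 1 (0.0565), control day 2 replicate 3 (0.125) and FHL2 day 2 replicate 3 (0.0744). The Wnt call held only without control day 0 replicate 3 or control day 2 replicate 3, with adjusted p up to 0.314 on leaving out 1 of the others. The endothelial call held only without control day 0 replicate 2 or FHL2 day 0 replicates 2 or 3, with adjusted p up to 0.175 without the others, and was lost after the correction for GC content (adjusted p = 0.0530). Mitochondrially encoded genes passed downward only after that correction (adjusted p = 0.0289, but adjusted p = 0.280 with an estimated correlation). NFAT5 and tonicity response genes had a median interaction of -0.040 (adjusted p = 0.957) and Nfat5 itself -0.16 (adjusted p = 0.967). Without the 3 libraries with the fewest genes the interaction of Nfat5 was called (log2 -1.1, adjusted p = 0.0304), and without a filter on low counts that of Cebpd was (-1.10, adjusted p = 1.04e-05).

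Tnc was the only gene called in the interaction by edgeR, where 996 genes had an unadjusted p under 0.05. DESeq2 called 73 genes and limma-voom 1. Its call was lost without any of 9 of the 12 libraries, with adjusted p from 0.0625 without FHL2 day 0 replicate 1 to 0.171 without control day 0 replicate 2. It held without control day 2 replicates 2 or 3 or FHL2 day 2 replicate 1. Without the 3 libraries with the fewest genes 243 genes were called.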

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

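The interaction tests were fixed before the data were examined. The tests of depth, transcript length, mitochondrially encoded genes, a swap of the lines and the construct, and the counts of other splits, were chosen after the results were seen.

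A direct test of the difference singled out 9 results in which the response to induction differed between the lines. Tnc, tenascin C, had an interaction of -1.30 on the log2 scale (SE 0.17, adjusted p = 0.0276), a call lost without any of 9 of the 12 libraries. By camera at its preset correlation, interferon-stimulated genes had a median interaction of 0.68 (adjusted p = 2.73e-23) and genes of G2 and mitosis 0.27 (adjusted p = 0.0143). Adipogenic transcription factors had -0.23 (adjusted p = 0.00837), mature adipocyte genes -0.45 (adjusted p = 0.00731) and glucocorticoid and cAMP response genes -0.18 (adjusted p = 0.00731). Collagens and extracellular matrix genes had -0.16 (adjusted p = 3.03e-05), Wnt targets -0.44 (adjusted p = 0.0253) and endothelial markers -1.08 (adjusted p = 0.0423). With an estimated correlation the interferon list passed (adjusted p = 0.0151) and the other 7 did not, with adjusted p from 0.0745 to 0.360.

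Chance cannot be excluded for the counts of the interaction. Of 100 splits of the libraries within the days, 27 gave at least the 1 gene of the real split, and the highest of the others gave 267. That split leaves the lines apart at both days and exchanges them at day 2, and the 80 splits that mix the lines at both days gave at most 21. As many lists as the real 8 were given by 7 of the 100 splits, the highest of the others giving 11. For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. At day 0 the real split gave 7 genes and the highest other 0 (1 of 10 splits as large), and 5 lists against 8 for the highest other (3 of 10 as large). At day 2 it gave 299 genes against 40 (1 of 10) and 8 lists against 3 (1 of 10). Induction gave 8246 genes against 0 (1 of 10) and 5 lists against 5 (3 of 10) in control, and 8087 genes against 0 (1 of 10) and 7 lists against 6 (1 of 10) in FHL2. For the 6 genes shared by both days, 1 of 100 splits, the real one, gave as many and the highest other gave 0. This does not bear on chance, since only 1 of the other splits called any gene at both days. For the 165 genes changed in opposite directions by induction and by FHL2 at day 2, 1 of 100 splits gave as many and the highest other gave 136. The 136 came from the split that exchanges the lines at day 2. The count follows the split of the day 2 libraries, since the 10 splits that keep the lines apart at day 2, the real one included, gave 48 to 165 and the 90 others at most 39, and the splits of 1 day are too few for a share under 0.05. Leaving out 1 library took the 165 to between 89 and 178.

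Day 2 libraries held fewer genes and lower levels of genes with low GC content. Depth in the sense of total counts is argued against, since the day 2 library with the most genes had 15831 after every library was thinned to the smallest total, below the 17312 of the lowest day 0 library. Thinning cannot show how many distinct molecules a library held, since reads were not tagged by molecule. Genes with 1 or 2 counts numbered 379 to 1251 per library at day 2 and 1448 to 2410 at day 0. Transcript length is argued against as the whole cause, since Spearman's rho between GC content and the change in control was at least 0.513 within each of 5 classes of length. A loss of RNA with low GC content in the day 2 libraries may have contributed and cannot be told apart from an effect of induction, because every day 2 library was induced and batches are not given in the sources used here. Mitochondrially encoded genes had a median log2 change in control 1.77 higher than nuclear genes of the same GC range (-0.34 and -2.11), which a loss that depends on GC content alone would not give, but mitochondrial RNA can differ from nuclear RNA in other ways.

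Mouse Fhl2 was not called higher in the libraries labelled FHL2, except at day 2 without the 3 libraries with the fewest genes (0.66 on the log2 scale, adjusted p = 0.0206). A swap of the lines at 1 of the days is argued against, since 84.9% of the genes called at day 2 had the same sign at day 0, where a swap would turn most signs. A construct whose transcript is not counted at the mouse gene, such as one of another species or with a recoded sequence, may account for the log2 fold change of 0.036 at day 0, and cannot be told apart from a construct that is not expressed, because the table holds no identifier other than mouse genes and the sequence of the construct is not given in the sources used here. A swap of both lines at both days would turn every direction given for FHL2 and was not testable with these counts. An effect of FHL2 itself on its own gene stays open as untested.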

How the results depend on the processing

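The corrections for GC content and for GC content and length, the fit without the 3 day 2 libraries with the fewest genes, the minimum mean of 5 CPM and the list tests in fits of only the groups compared were chosen after seeing the data, and the other alternatives before. Depth limits what can be seen of genes near the floor: a gene absent from a group of 3 libraries is bounded by 3 counts over the group. RLE scaling left every count of genes, lists and shared genes within 1.5 times its reported value. So did 1 CPM in at least 3 libraries and a minimum mean of 5 CPM for the counts of genes and shared genes, and lists were not tested with these filters.

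Genes called at day 0, 7 as reported, numbered 69 without a filter on low counts, 93 with DESeq2, 18 with limma-voom, 246 with only the groups compared, where the spread is smaller, 2 at an absolute log2 fold change of at least 1, 13 with the GC correction, 34 with the GC and length correction and 135 without the 3 day 2 libraries with the fewest genes. Genes called at day 2, 299 as reported, numbered 846 without a filter, 997 with DESeq2, 39 with only the groups compared, where the spread is larger, 86 at an absolute log2 fold change of at least 1, and 1606 without the 3 libraries. A log2 fold change of at least 1 left 5096 genes of induction in control and 4912 in FHL2. Genes of the interaction, 1 as reported, numbered 2 with upper-quartile scaling, 91 without a filter, 73 with DESeq2, 6 with the GC correction, 7 with the GC and length correction and 243 without the 3 libraries. The cause of the differences between tools was not tested.

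Lists past the threshold numbered 0 at day 0, 2 at day 2, 3 and 2 with induction in control and FHL2 and 1 in the interaction for camera with an estimated correlation, which allows for genes that vary together, against 5, 8, 5, 7 and 8 as reported. With fry, which does not compare a list with other genes, they numbered 15 and 17 with induction and 3 in the interaction. The GC correction gave 12 lists with induction in each line, and the GC and length correction 12 in control and 13 in FHL2. Without the 3 libraries, 2 lists passed at day 0.

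Genes shared by both days, 6 as reported, numbered 32 without a filter, 54 with DESeq2, 10 with limma-voom, 10 with only the groups compared, 1 at an absolute log2 fold change of at least 1, 11 with the GC correction, 21 with the GC and length correction and 63 without the 3 libraries. Genes changed in opposite directions by induction and FHL2, 165 as reported, numbered 401 without a filter, 478 with DESeq2, 30 with only the groups compared, 43 at an absolute log2 fold change of at least 1 and 627 without the 3 libraries. The cause was not tested.

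Leaving out 1 library in turn gave 1 to 5 genes and 3 to 8 lists at day 0, 146 to 404 genes and 4 to 9 lists at day 2, 0 to 6 genes and 3 to 7 lists in the interaction, 1 to 7 genes shared by both days and 89 to 178 changed in opposite directions. Counts of induction stayed between 7092 and 8255 in control and between 7058 and 8120 in FHL2. On leaving out each library of a comparison, 1 of 7 named calls held at day 0, 22 of 45 at day 2, 36 of 37 with induction in control, 32 of 34 in FHL2 and 0 of 1 in the interaction. The 45 include genes of lists chosen after the values were seen.

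Signs turned for Fhl2 with the GC and length correction (-0.013 at day 0 and -0.032 at day 2) and on leaving out 1 library (-0.020 to 0.080 at day 0, -0.19 to 0.35 at day 2), for Akr1b3 at day 2 without the 3 libraries (0.053) or 1 library (-0.26 to 0.093), and for Nfat5 in the interaction without 1 library (-0.54 to 0.081), none of which was called. With induction in control, signs turned with the GC correction and with the GC and length correction for Nfat5 (0.037 and 0.50), Slc5a3 (0.12 and 0.50), Dlk1 (-0.45 and -0.31) and Tnc (-0.40 and -0.085). Tnc, near 0, also turned with RLE scaling (-0.0047), DESeq2 (-0.0046), no filter (-0.0067) and without 1 library (-0.053 to 0.21). In FHL2 the GC and length correction turned Nfat5 (0.26), Slc5a3 (0.31) and Mki67 (0.37).

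The replicate number as a block gave 11 genes at day 0. Whether the numbers pair the libraries stays open. Of 18 pairs with the same number, 5 had a correlation of residuals over 0.1, and 7 of 12 libraries were closest to one of their own number. Correlations ranged from -0.14 to 0.26 in pairs with the same number and from -0.37 to 0.24 in the 36 others.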

Other observations

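The lists of glycolysis, other hypoxia-response genes, proteasome subunits and complement genes, and all tests in this part, were chosen after the values were seen, so their p-values are not those of lists fixed in advance. Adjusted p-values of these lists are over the 4 lists within a comparison.

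Glycolysis genes were lower in the libraries labelled FHL2 at day 2, when Fhl2 itself did not pass the test. Of 18 genes, 17 were lower and 12 were called, with a median log2 fold change of -0.60 (camera adjusted p = 1.40e-23, and adjusted p = 0.00361 with an estimated correlation). The enolase Eno1 had 1088 ± 85.7 against 1694 ± 144 CPM (log2 fold change -0.64, SE 0.086, adjusted p = 0.00269), the triose phosphate isomerase Tpi1 1480.1 ± 192 against 2329.8 ± 166 CPM (log2 fold change -0.65, SE 0.10, adjusted p = 0.00529) and the phosphofructokinase Pfkl, which sets the pace of the pathway, 431 ± 81.7 against 832 ± 70.1 CPM (log2 fold change -0.95, SE 0.12, adjusted p = 0.00212). Pgam1 had -1.06 (SE 0.15, adjusted p = 0.00338) and Gapdh -1.45 (SE 0.33, adjusted p = 0.0379), whose reads cannot be told with certainty from those of its many pseudogene copies. Without control replicate 1 Gapdh had -0.68 (adjusted p = 0.0501), and its call was also lost without FHL2 replicates 1, 2 or 3 (0.0692, 0.0958 and 0.0804), in a fit of the day 2 libraries alone (0.114), with limma-voom (0.0506) and with the replicate block (0.0574). At day 0, 18 of 18 were lower, 0 called by edgeR, with a median of -0.25 (adjusted p = 0.0101 with an estimated correlation). From day 0 to day 2, 15 of them rose in control and 14 in FHL2, and the interaction had a median of -0.33 (adjusted p = 8.31e-07, but adjusted p = 0.117 with an estimated correlation).

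Genes that cells raise when oxygen is low, which share regulators with glycolysis, leaned lower too at both days. Of 23 such genes outside glycolysis, 21 were lower and 8 called, with a median of -0.57 (adjusted p = 0.0260 with an estimated correlation, but adjusted p = 0.0572 with it in a fit of the day 2 libraries alone). At day 0 21 were lower, 0 called by edgeR, with a median of -0.24 (adjusted p = 0.0483 with an estimated correlation). Egln1, an oxygen sensor, had 73.3 ± 16.4 against 159 ± 28.6 CPM (log2 fold change -1.12, SE 0.16, adjusted p = 0.00463), the carbonic anhydrase Car9 9.58 ± 1.82 against 32.6 ± 14.2 CPM (log2 fold change -1.77, SE 0.31, adjusted p = 0.0117) and the cytokine Mif 211 ± 21.8 against 461 ± 55.3 CPM (log2 fold change -1.12, SE 0.11, adjusted p = 0.000198). Proteasome subunits had a median of 0.14 over 31 genes (adjusted p = 0.521 with an estimated correlation) and complement genes -0.072 over 11 (adjusted p = 0.521). The median of the proteasome subunits turned to -0.059 without FHL2 replicate 3. That of the complement genes ranged from -0.22 to 0.21 on leaving out 1 library. At day 0 complement genes had a median of -0.18 with 0 called by edgeR (adjusted p = 0.000934, and adjusted p = 0.0483 with an estimated correlation).

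A hypothesis is that the lower glycolysis genes at day 2 may be a difference between the lines, and not an effect of the GC content trend or of 1 library. The GC content trend is argued against, since camera still gave a p-value of 4.27e-24 before adjustment (adjusted p = 1.71e-23) and a median of -0.60 after the correction for GC content, with 13 genes called lower. A single day 2 library is argued against, since the largest camera p before adjustment on leaving out each of the 6 libraries was 3.62e-17, with 7 (without control replicate 2, and without FHL2 replicate 2) to 11 genes called. A fit of the day 2 libraries alone called 5 of 17 (adjusted p = 0.0169 with an estimated correlation). Neither culture conditions nor the effect of the construct were tested, and they cannot be separated here.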
